A study of Homo sapiens with 2 samples.

How the data were processed

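The series holds 2 expression arrays of a human hepatocellular carcinoma (HCC) cell line, PLC8024. Per the labels' protocols, cells lacking the surface marker CD133 were obtained by flow cytometric sorting, transduced with a lentivirus carrying the microRNA miR-130b or with an empty lentiviral vector, and their total RNA was extracted with Trizol and hybridised after biotin labelling. The source label of the miR-130b sample calls the treatment a transfection, while its treatment protocol and the series design call it lentiviral. The groups were taken from the sample titles, and each group holds 1 array. There is no replicate of either condition, so no p-value, standard error or test between the conditions was computed, and every difference given is a difference between these 2 arrays. What separates the 2 cultures other than the vector cannot be removed from it.

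The authors deposited a table of 54675 probe sets with 1 log2 expression value per probe set and array. RMA, which corrects the background, normalizes the arrays to a shared distribution and summarises the probes of a set on the log2 scale, is named without a version in the submitters' processing notes. The settings of that step and the arrays normalized together are not given in the sources used here. The column medians were 4.89 for the empty vector and 4.88 for miR-130b on the log2 scale. RMA values carry a residual background and compress the fold of dim probe sets, and the table gives no detection call. The precision is limited by the number of arrays. Exactly the same value stood in both arrays for 4.2% of the non-control probe sets.

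Probe sets were named through GEO's platform annotation. Of 54613 non-control probe sets, 41091 had 1 gene symbol, 1801 had several and 11721 had none. Probe sets with several symbols named no gene, so list members covered by no probe set of their own were not analysed here. Entrez identifiers of 41037 of the 41091 probe sets were found in the RefSeq gene table, and no symbol changed by that match. No genomic positions or transcript sequences were used, so the planned search for matches to nucleotides 2 to 8 of miR-130b in 3' untranslated regions was not run.

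From the deposited values, the log2 difference miR-130b minus empty vector was computed per probe set. A gene counted as measured when its brighter array was at or above 4.88, the median of all non-control probe sets over both arrays. This left 13260 genes, and each was represented by its measured probe set with the highest mean. The only error the design offers is technical: among 6047 genes with at least 2 measured probe sets, the pooled SD of the difference between probe sets of a gene was 0.202 on the log2 scale. Genes were counted beyond 2-fold and beyond 1.5-fold (0.58 on the log2 scale), as rules of size, not as tests.

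Before the data were examined, 23 gene lists were fixed for this cell type and treatment, together with the rule for naming genes and all alternatives not described as chosen later. The list of reported miR-130 family targets came from general knowledge, and it includes TP53INP1, which published work on miR-130b in liver tumour cells concerns, so TP53INP1 is not independent of the study. For each list, the median difference of the measured members was set against the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. Its percentile describes these 2 arrays. A list outside the 2.5 to 97.5 percentile range is described as apart from random lists, and 1.15 of 23 lists are expected there by chance if their genes were drawn independently. The 95% interval of a list median is the binomial interval over its genes, which are not independent replicates.

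The named genes are the 12 with the largest difference in each direction whose measured probe sets all had the same sign, up to 4 members of each list by absolute difference, TP53INP1, PROM1 and DICER1 whatever their values, and the genes of the array's human control probe sets. Any other gene named was chosen after its values were seen and is marked so. On simulated arrays with known answers over 13264 genes, all 50 genes planted at 1.5 on the log2 scale were found beyond 2-fold, and 3.0% of 200 random lists of 25 genes fell outside the percentile range. The simulated noise was capped and its sign drawn independently for each probe set. Recovery was therefore all but fixed in advance, and the simulation checks the computation, not the error of these arrays. The alternatives were no floor, a floor at the 75th percentile (6.98), the mean of all measured probe sets of a gene, leaving out probe sets with the suffixes _x_at and _s_at, and centring by a loess curve with a span of 0.3. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.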

Results

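Expression profiles were compared between CD133-negative PLC8024 hepatocellular carcinoma cells carrying lentiviral miR-130b and CD133-negative PLC8024 cells carrying an empty vector. CD133, the product of PROM1, is a surface marker used to isolate tumour-initiating cells in liver cancer, and miR-130b is a microRNA that lowers the level of target transcripts. The comparison asks which transcripts differ when miR-130b is overexpressed in the CD133-negative fraction. One array was hybridised per condition, so no value below has a replicate error and no difference was tested. Over 54613 non-control probe sets the arrays had a Pearson correlation of 0.993 and a Spearman correlation of 0.988 across probe sets, which are not independent replicates. The median difference of the 13260 measured genes, miR-130b minus empty vector on the log2 scale, was 0.031. The mature microRNA itself was not analysed here.

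Among named genes, the largest differences were all decreases in the miR-130b array. SPINK1, a secreted trypsin inhibitor, was 98.9-fold lower, at 3.96 in the miR-130b array against 10.6 in the empty vector array on the log2 scale. NPPB, which encodes B-type natriuretic peptide, was 35.2-fold lower, and the cell adhesion gene FLRT3 was 25.4-fold lower, with both of its measured probe sets lower. PHLDB2, PLK2, the endodermal transcription factor GATA6, the protease inhibitor SERPINE2, the metallothionein MT1M, the LIM-domain gene FHL2, the chemokine gene CXCL6, the thyroxine carrier TTR and the long non-coding RNA PCAT4 completed the 12 genes with the largest decreases. Their log2 differences ran from -4.45 for PHLDB2 to -3.29 for PCAT4. Of these 12 genes, 10 lay below the expression floor in the miR-130b array, where the remaining background compresses the fold, and 11 rested on 1 measured probe set.

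In total, 201 genes were at least 2-fold lower in the miR-130b array and 0 of 13260 were at least 2-fold higher. At 1.5-fold, 356 genes were lower and 39 were higher. The SD between probe sets of the same gene was 0.202 on the log2 scale, and it holds no variation between cultures. Among the genes at least 2-fold lower, 77 had further measured probe sets that had not been used to select them. Of these 132 probe sets, 125 were also lower, with a median difference of -1.08. That count leaves out probe sets below the floor in both arrays. Without a floor, 236 of 302 further probe sets were lower, with a median of -0.29. Among the genes at least 1.5-fold higher, 8 of 12 further probe sets were also higher, with a median of 0.23. The number of genes at least 2-fold lower was 117 of 8277 when only genes above the 75th percentile of all values were kept.

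**Figure D1:**
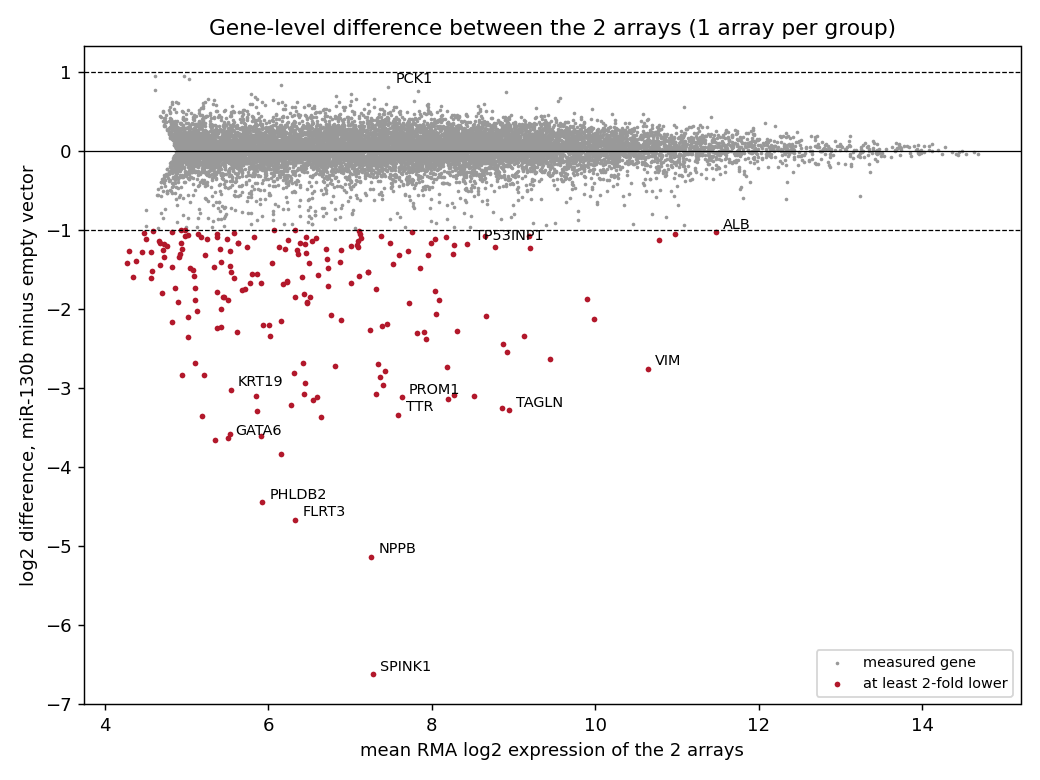
Log2 difference between the miR-130b and the empty vector array (y axis) against the mean RMA log2 expression of both arrays (x axis), 1 point per measured gene, with dashed lines at 2-fold and the 201 genes at least 2-fold lower in red. The spread extends downwards to -6.63 for SPINK1, and no gene lies above the upper line.

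The 12 genes with the largest increases ranged from 1.58-fold to 1.93-fold. PCK1, the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, was higher by 0.81 on the log2 scale, the AP-1 subunit gene FOSB by 0.75 and the orphan nuclear receptor gene NR4A3 by 0.74. KLHL15 was the brightest of the 12, at 9.23 in the empty vector array and 9.90 in the miR-130b array. RASGEF1A and TAF4B were higher by 0.72 and 0.69. The other 6 genes, RFPL3S, TMEM200A, GABPB2, KIAA1107, HMCN1 and ATAD5, lay below the 75th percentile of all values in both arrays. Of the 12, 11 rested on 1 measured probe set.

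Among reported targets of the miR-130 family, TP53INP1, a p53-inducible gene with pro-apoptotic activity, showed the largest decrease by the brightest probe set. This probe set was 2.27-fold lower, a difference of -1.18 on the log2 scale from 9.02 to 7.84. A further TP53INP1 probe set just above the floor differed by -0.07, and one below the floor by 0.13, so the decrease rests on 1 probe set. BMPR2, a BMP receptor, differed by -0.80 on the log2 scale in its brightest probe set and by -0.41 in the mean of its probe sets. The receptor gene ACVR1 differed by -0.47 and TIMP2 by -0.32 in its brightest probe set, with -0.65 and -0.95 in the 2 others. With the mean of probe sets, TIMP2 had -0.64 and TP53INP1 -0.63. Of the 24 measured members, 2 were at least 1.5-fold lower, 0 were at least 1.5-fold higher and 22 lay between. The list's median was -0.03 with a 95% interval from -0.18 to 0.11, at the 5.75 percentile of random lists. It lay at the 23.4 percentile without TP53INP1, and at the 1.22 percentile with the floor at the 75th percentile.

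DICER1, the enzyme that cuts microRNA precursors, differed by -0.07 on the log2 scale in its brightest probe set and by 0.11 in each of the 2 other measured ones. No member of the microRNA pathway list, 14 genes measured, reached 1.5-fold. LIN28B, a repressor of let-7 maturation, differed by -0.35, TNRC6B by -0.32, AGO3 by 0.31 and TNRC6C by 0.30, or 0.11 in the mean of its probe sets. The list's median of 0.03 stood at the 47.5 percentile of random lists.

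The sort marker PROM1 was 8.71-fold lower in the miR-130b array, at 6.07 against 9.19 on the log2 scale, from 1 probe set. KRT19, a keratin of biliary and progenitor cells, differed by -3.03, the stem cell receptor gene LGR5 by -1.27 and the adhesion molecule gene EPCAM by -1.16. In the miR-130b array KRT19, LGR5 and EPCAM lay below the floor of 4.88, at 4.02, 3.66 and 4.09. LGR5 and EPCAM stood close to that floor in the empty vector array, at 4.93 and 5.25. LGR5 differed by only -0.28 without a floor, where another probe set represents it. These 4 genes were the only ones of 25 measured liver tumour-initiating cell and stemness markers beyond 1.5-fold, and 21 differed by less. The list's median was -0.07 with a 95% interval from -0.30 to -0.01, at the 0.69 percentile of random lists and at the 1.61 percentile without PROM1. In the overlapping list of biliary and progenitor genes, 5 of 14 were at least 1.5-fold lower and 0 higher, among them the secreted phosphoprotein gene SPP1 with -1.91. That list stood at the 1.14 percentile, and at the 6.88 percentile without PROM1. Without probe sets carrying the suffixes _x_at or _s_at it stood at the 84.5 percentile, with 8 members left.

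Mesenchymal genes showed the lowest median of the 23 lists. The actin-binding gene TAGLN was 9.75-fold lower, N-cadherin (CDH2) was 7.84-fold lower (differences of -2.97 and -1.77 in its 2 probe sets), the intermediate filament gene VIM was 6.77-fold lower and the matrix gene SPARC differed by -1.47 on the log2 scale. Of 13 measured members, 6 were at least 1.5-fold lower and 0 were higher, and the median of -0.41 lay below all 10000 random lists. The median's size depended on the genes kept: it was -0.20 over 20 genes without a floor, -0.22 over 6 without the suffixed probe sets and -2.76 over 5 with the floor at the 75th percentile. TAGLN's probe sets disagreed: a dimmer one differed by -0.05, while the 2 others differed by -3.28 and -4.13. Epithelial genes were not higher. KRT8 differed by -1.05 and E-cadherin (CDH1) by -0.82, 4 of 16 measured members were at least 1.5-fold lower and 0 higher, and the median of -0.09 stood at the 1.23 percentile, or at the 57.3 percentile without probe sets carrying these suffixes. Among stromal and endothelial markers, COL1A2 differed by -3.08 while THY1, PECAM1 and TEK differed by 0.24, 0.21 and 0.16 (THY1 by 0.08 and PECAM1 by -0.03 in the mean of their probe sets), and the list stood at the 26.2 percentile with 8 members measured. Leukocyte markers, 7 measured, stood at the 28.3 percentile, with no member beyond 1.5-fold. Their LYZ differed by -0.32 in its brightest probe set and by -1.72 in a dimmer one.

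Hepatocyte genes were mostly within 1.5-fold. TTR was 10.1-fold lower and ALB, which encodes serum albumin, was 2.05-fold lower, from 11.99 to 10.96 on the log2 scale in its brightest probe set, with differences of -1.56 and -2.38 in the 2 other measured ones. These 2 were the only ones beyond 1.5-fold among 28 measured, and none was higher. APOA1 differed by -0.51 and RBP4 by -0.43, but APOA1's probe sets disagreed, with 0.11 in the one that carries no cross-hybridisation suffix. The median of -0.04 stood at the 0.82 percentile of random lists and was 0.08, at the 81.2 percentile, without _x_at and _s_at probe sets.

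Several signalling lists had a few strongly lower members. Of 26 TGF-beta and BMP pathway genes, 5 were at least 1.5-fold lower and 0 higher. TGFB2 differed by -1.79 and, in a dimmer probe set, by -0.81, INHBA by -0.86 and the TGF-beta-induced matrix gene TGFBI by -0.80. TGFB1 differed by -1.01 in one probe set and by 0.00 in another, which stood just above the floor, at 4.94 in both arrays. The list's median of -0.16 lay below all random lists, and was 0.00, at the 18.8 percentile, without _x_at and _s_at probe sets. The Notch ligand gene JAG1 was 3.68-fold lower in its brightest probe set, with differences from -0.07 to -2.88 in the others measured. It was the only one of 19 Notch and hedgehog pathway genes beyond 1.5-fold, and HEY1, SMO and NOTCH2 differed by -0.45, -0.43 and -0.30. That list stood at the 0.865 percentile, but inside the range of random lists without a floor (3.71), with the floor at the 75th percentile (4.39) and without the suffixed probe sets (15.9). Among 16 Wnt pathway target genes, the secreted Wnt inhibitor DKK1 differed by -2.78 and LGR5 by -1.27 (-0.28 without a floor), whereas the transcription factor gene LEF1 was higher by 0.59 and BAMBI differed by -0.57. The Wnt list stood at the 35.3 percentile, with a median of 0.01 and a mean of -0.25.

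Proliferation and cell death genes stayed close to the bulk of genes. None of 36 measured cell cycle genes reached 1.5-fold, with CCND1 at -0.46, CCNE1 at 0.43, MCM4 at -0.40 (-0.12 in the mean of its probe sets, which disagree in sign) and TPX2 at -0.34, and the list stood at the 24.0 percentile. Among 24 p53 target genes, PLK2 was 12.6-fold lower and TP53INP1 was 2.27-fold lower. TP53I3 differed by -0.56 and ZMAT3 by -0.55, or -0.28 in the mean of its probe sets. The p53 list's median of 0.05 and mean of -0.22 differed in sign, and the median stood at the 65.0 percentile. Of 22 apoptosis regulators, the BH3-only gene BID was 2.40-fold lower, with all 3 measured probe sets lower. XIAP, CASP6 and BCL2L1 differed by 0.27, -0.24 and -0.22 (XIAP by 0.03 in the mean of its probe sets), and the list stood at the 39.1 percentile. Of 12 drug efflux transporters, ABCB1 differed by -0.83 and none was 1.5-fold higher. ABCB10, ABCC5 and ABCA3 differed by 0.37, -0.30 and 0.25 (ABCC5 by 0.11 and 0.07 in its 2 other probe sets), and the list stood at the 73.0 percentile.

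Metabolic, stress and innate immune lists held few genes beyond 1.5-fold. Of 20 cholesterol and fatty acid synthesis genes, the desaturase gene FADS2 was 3.37-fold lower and was the only one beyond 1.5-fold. MVD, HMGCS1 and FASN differed by -0.46, -0.23 and -0.22 (HMGCS1 by -0.76 in a dimmer probe set), and the list stood at the 0.09 percentile with a median of -0.09. Interferon-stimulated genes, 23 measured, stood at the 69.4 percentile: MX2 differed by -2.01 on the log2 scale, while IFIH1, EIF2AK2 and IFI6 differed by 0.42, 0.37 and 0.27. None of 23 hypoxia and glycolysis genes reached 1.5-fold (84.0 percentile, or 98.9 without the suffixed probe sets), with SLC2A3 at 0.55 and PFKFB3 at 0.35. None of 21 stress response genes did (79.0 percentile), with VLDLR at -0.56 and HERPUD1 at 0.35, or -0.19 in a dimmer probe set. Among 20 NF-kappaB and inflammatory genes, IL11 was highest at 0.58, just under 1.5-fold, and TNFAIP2 was lowest by the brightest probe set, at -0.53 (7.46 percentile). TNFAIP2's other probe set differed by 0.06, and with the mean of probe sets CXCL5 had -0.70 against -0.24 for TNFAIP2. Of 21 immediate early genes, FOSB alone passed 1.5-fold, with KLF10 at 0.34 and JUNB at -0.29 (44.8 percentile).

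**Figure D2:**
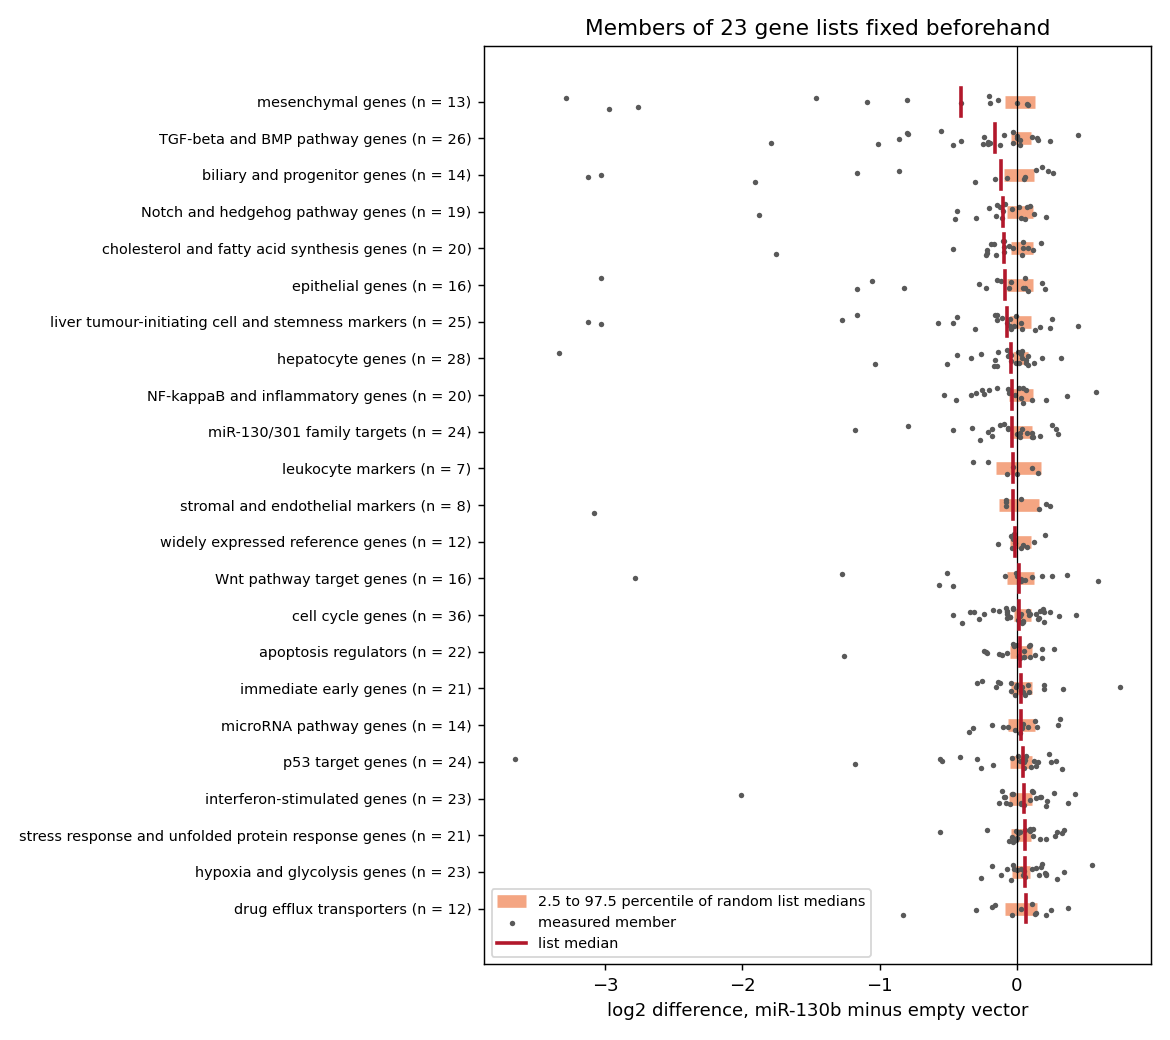
Log2 difference between the miR-130b and the empty vector array (x axis) for the measured members (grey points) of 23 gene lists, with each list's median (red line) and the 2.5 to 97.5 percentile range of the medians of 10000 random lists (orange bar). In all, 8 lists lie below their range, led by mesenchymal genes with a median of -0.41, and none lies above.

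In total, 8 of the 23 lists lay below the range of random lists and 0 above, where 1.15 outside it are expected for lists of genes drawn independently. Members of a list can move together, so the excess over chance cannot be measured here. Without the suffixed probe sets, 4 lists lay below and 1 above. The 4 include the reported miR-130 family targets (1.34 percentile), which lay inside the range with all probe sets. The lists share members, such as KRT19, PROM1, EPCAM and LGR5, so they are not independent of each other. Widely expressed reference genes, 12 measured, had a median of -0.02 at the 12.5 percentile, with TBP, YWHAZ, GUSB and TFRC at 0.20, -0.13, 0.13 and 0.07.

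Control probe sets differed between the arrays. Of 27 probe sets of the poly-A spike-in transcripts, which are added to RNA before labelling, 26 were lower in the miR-130b array, with a median of -0.24 and with 1 trp probe set, below the floor, higher by 0.12, whereas 17 of 18 hybridisation spike-in probe sets were higher, with a median of 0.09. The 3' to 5' ratio of ACTB was 2.41 in the miR-130b array and 1.95 in the empty vector array, and that of GAPDH was 1.52 and 1.37. Of 14 control pairs of 3' and 5' probe sets, 12 had the 5' probe set lower relative to the 3' probe set in the miR-130b array, down to -0.50 on the log2 scale. The exceptions were HUMRGE with 0.42 and TrpnX, below the floor, with 0.01. The dap and DapX pairs carry the name of the same spike-in, as do those of lys, phe and thr, so the pairs are not independent.

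**Figure D3:**
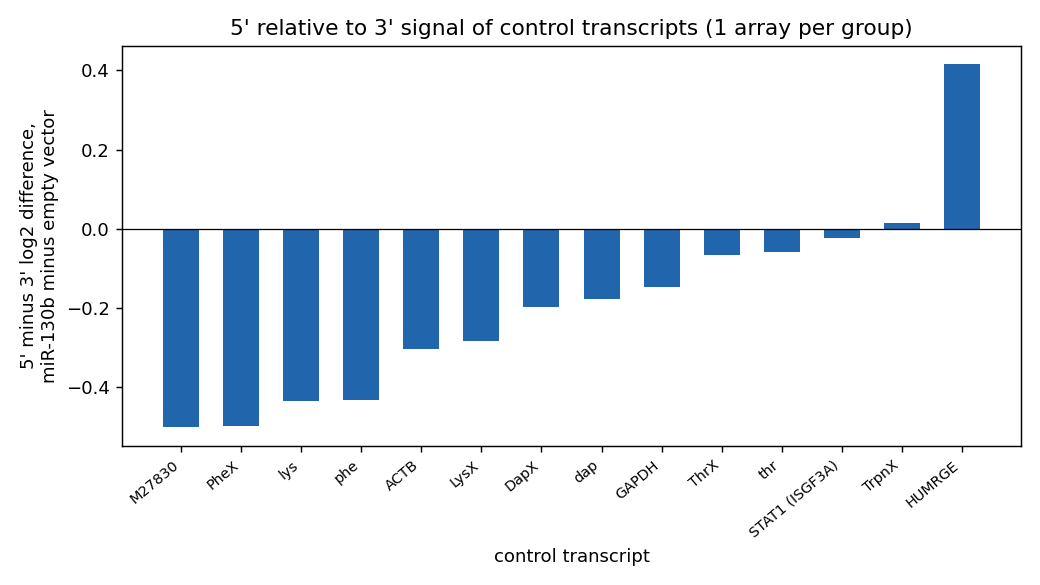
Log2 difference between the miR-130b and the empty vector array of the 5' probe set minus that of the 3' probe set (y axis) for 14 pairs of control probe sets (x axis), 1 array per group. The bars run from -0.50 for M27830 and PheX to 0.42 for HUMRGE, and 12 of the 14 lie below 0.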

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

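All tests of explanations below were chosen only after the result was seen. Among the 11721 probe sets without a gene name, which no gene-level comparison above uses, 3 were at least 2-fold higher in the miR-130b array than in the control array, while no probe set with 1 gene name and above the floor was. Probe set 1555623_at was higher by 3.61 on the log2 scale, from 5.08 to 8.69, which is 12.2-fold and the largest increase on the arrays. Probe set 1558048_x_at was higher by 1.21, from 3.74 to 4.95. Probe set 237746_at was higher by 1.14 but stayed below the floor, at 4.85. Of the unnamed probe sets above the floor, 26 were at least 2-fold lower. No replicate exists to check these increases.

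The one-sided difference, 201 genes at least 2-fold lower and 0 higher, was set against 3 technical explanations. Loss of 5' signal in the miR-130b array stays open. The further measured probe sets of the lower genes had a median of -1.08. The largest 5' loss of a control transcript, relative to its 3' probe set, was -0.50. That does not bound the loss in other transcripts, and no probe positions were used. Without a floor the median of 302 further probe sets was -0.29, above the -0.50 of the controls, and 170 of these lay below the floor in both arrays. Leaving those out puts the floor back, so the -1.08 of the others is not a second result. A level-dependent scaling left in the deposited values does not account for the one-sided difference, since 202 genes were at least 2-fold lower and 0 higher after loess centring. RMA had already given the arrays a shared distribution. Loess centring could therefore change little, and it cannot test scaling before or within RMA. Stromal cells, endothelial cells or leukocytes in the empty vector culture stay open: 15 measured markers had a median of -0.03, but COL1A2 differed by -3.08 and 18 further markers lay below the floor. Repression by miR-130b is open too: the reported targets without TP53INP1 stood at the 23.4 percentile, and no site search was run. A second population of tumour cells in the empty vector culture was not tested.

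PROM1, the marker the cells were sorted against, was high in the empty vector array of CD133-negative cells and 8.71-fold lower in the miR-130b array. A candidate explanation is more CD133-positive tumour-initiating cells in the empty vector culture when RNA was taken. This stays open: the 24 other measured markers of such cells had a median of only -0.06, at the 1.61 percentile of random lists, with 3 of them at least 1.5-fold lower and 21 within 1.5-fold. PROM1 has 1 probe set here, and an effect of miR-130b on PROM1 stays open and untested.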

How the results depend on the processing

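Results were recomputed without a floor, with the floor at the 75th percentile, with the mean of a gene's probe sets, without probe sets ending in _x_at or _s_at, and after loess centring; the settings that leave out 1 list member (TP53INP1, PROM1 or TAGLN) were chosen after seeing the data. No gene was 2-fold higher under any of these 5 settings, and the number at least 2-fold lower ranged from 117 to 204. With the floor at the 75th percentile, 8277 genes remained to be counted, of which 117 were at least 2-fold lower, 16 at least 1.5-fold higher and 192 at least 1.5-fold lower. Without the _x_at and _s_at probe sets, the medians of hepatocyte, biliary and epithelial genes turned to 0.08, 0.10 and 0.05 with 16, 8 and 10 members left, and that of reference genes moved to 0.10 with 8 left; the lists then held fewer genes. Also without them, the TGF-beta list stood at the 18.8 percentile and the Notch and hedgehog list at the 15.9 percentile, inside the range of random lists, and the reported miR-130 family targets at the 1.34 percentile, below it. The hepatocyte list was also inside the range without a floor (4.60) and with mean probe sets (11.5), and the Notch and hedgehog list without a floor (3.71) and with the higher floor (4.39). Hypoxia and glycolysis genes stood above the range, at the 98.9 percentile, without these probe sets. In all, 134 of 141 recomputed counts, medians and spreads stayed within 1.5 times the count or inside the median's interval, which is wide for short lists: the median of biliary genes was -0.12 and became -1.39 over 6 genes with the higher floor. Of 118 recomputed list percentiles, 13 changed their side of the random range. The 50 named genes beyond 1.5-fold kept their direction in 215 of 216 recomputed values. The exception is TGFB1, at 0.00 without _x_at and _s_at probe sets, from a probe set just above the floor. In 6 of the 216 the difference was under 1.5-fold: TGFB1 there and with mean probe sets (-0.51), TAGLN without _x_at and _s_at probe sets (-0.05), BMPR2 with mean probe sets (-0.41), LEF1 after loess centring (0.56) and LGR5 without a floor (-0.28). TP53INP1 differed by -0.63 with mean probe sets. The site search for both strands of miR-130b and its alternatives were not run, since no transcript sequences were used here. No paired analysis was possible because each group holds 1 array. Replicates could not be left out in turn for the same reason, and dim probe sets limit the folds.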

Other observations

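The gene families, SMARCA4, ITGAV and the test of cross-hybridisation in this part were chosen after the values were seen, the families by gene symbol. Metallothioneins, which bind zinc and copper, were lower together: 8 of 9 measured genes were at least 2-fold lower, from MT1M with -3.58 and MT1E with -3.26 (-1.43 in its other probe set) to MT1G with -2.09, and MT4 differed by 0.15. Their median was -2.55. Among 16 histone genes, 8 were at least 2-fold lower and 0 higher, including H2AC6 with -2.95, H2BC12 with -2.34 and H1-2 with -2.08. The 8 were H2AC6, H1-2 and all H2B genes among the 16. The others, with all H3 and H4 genes among the 16 and further H2A and H1 genes, ran from -0.36 to 0.14. The median of -0.91 lies in the gap between H2BC21 with -1.47 and H2AC25 with -0.36. Of the 8 lower genes, 6 rest on probe sets with the suffix _x_at or _s_at. Serpins, a family of protease inhibitors, had 6 of 18 members at least 1.5-fold lower, including SERPINA5 with -1.54 and the collagen chaperone SERPINH1 with -1.37, with a median of -0.30.

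Of 19 measured collagens, 5 were at least 1.5-fold lower and 0 higher, with a median of -0.08. COL5A2, COL1A2, COL12A1 and COL2A1 differed by -3.10, -3.08, -1.89 and -1.74 on the log2 scale, while COL1A1 differed by -0.08 in its brightest probe set and by -1.68, -0.88 and 0.38 in the other measured ones. Of 3 lysyl oxidases, which cross-link collagen, LOXL2 differed by -2.69 in one probe set and by -0.17 in another, LOXL4 by -1.32 and LOX by -0.41. By contrast, 57 ribosomal protein genes had a median of 0.00 and no member beyond 1.5-fold, and 282 ZNF genes had a median of 0.05. SMARCA4, the ATPase of the SWI/SNF chromatin remodelling complex and widely expressed, differed by -1.54 on the log2 scale in its brightest probe set. All 7 of its measured probe sets were lower, but they ran from -0.03 to -2.18. Integrin alpha-V (ITGAV) differed by -1.13 from a level of 11.3, and ITGA1 and ITGA2 by -1.08 and -1.02; these 3 were the only ones at least 2-fold lower of 22 integrin subunits, whose median was -0.03. The median of 16 keratins was 0.01, but 2 were at least 2-fold lower, KRT19 with -3.03 and KRT8 with -1.05. KRT222 was the only one at least 1.5-fold higher, with 0.60. Most of the 16 lay below the 75th percentile of all values in both arrays, so the median mainly describes dim genes.

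Metallothionein probe sets may read one another's transcripts, since 10 of the 12 measured carry the suffix _x_at, which marks cross-hybridisation. Of the 2 that do not, that of MT1M differed by -3.58 and that of MT4 by 0.15. With so few specific probe sets, a fall of several metallothionein genes and a fall of 1 abundant gene read by all of them cannot be told apart, although MT1M's own probe set was lower.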
